A study of Danio rerio with 12 samples.

How the data were processed

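The data are 12 Quartz-seq libraries from adult wild-type zebrafish kidney, sequenced on an Illumina NextSeq instrument per the labels. Quartz-seq amplifies messenger RNA from small samples by reverse transcription from an oligo-dT primer, tailing of the product and PCR. Per the labels' protocols, RNA was extracted from sorted cells before amplification, and no molecular identifiers are described, so reads copied by PCR are not independent molecules. Reads were processed with HISAT2 2.1.0 and Subread 1.6.4 on zebrafish genome build GRCz11, per the submitters' processing notes; their order and settings are not given in the sources used here. The authors deposited one table per library with CPM, read counts scaled to a common library total, for 32047 gene identifiers, to 2 decimals in the niche libraries and 1 decimal in the double positive libraries. Each library's values summed to the same total within rounding, as CPM do.

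The libraries fall into 6 groups of 2 by their titles. The niche set holds ZKS cells, pericytes (titled by pdgfrb) and sinusoids (titled by high uptake of acetylated low-density lipoprotein, Ac-LDL). The double positive (DP) set holds gata2a+ runx1+ cells that were uncultured, co-cultured with ZKS cells, or co-cultured with ZKS cells plus IWR-1-endo and Thpo. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The same replicate numbers occur in every group, and no label says that they mark a shared animal or day. Columns belonging to samples of other series numbered 0.

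Depth was read from the values. In the niche libraries the CPM values were multiples of what 1 read is worth, and 100% of values came out whole within a tolerance of 0.1 read. The recovered depth was 9260867 and 9880702 reads for the ZKS libraries, 7006341 and 6984492 reads for the pericyte libraries, and 13372200 and 16242092 reads for the sinusoid libraries. The step of ZKS replicate 2, 0.101 CPM, lay close to 0.1 CPM, where low values alone cannot tell a read from rounding. Over all its values 100% came out whole with its own step, against 39.8% with a step of 0.1 CPM. A count of 3 reads was taken as the floor, per library, which was 0.324 and 0.304 CPM in the ZKS libraries, 0.428 and 0.43 CPM in the pericyte libraries, and 0.224 and 0.185 CPM in the sinusoid libraries. Where every library of a niche group was at 0, the fold is given as a lower bound against the higher floor of that group (for ZKS, that of replicate 1). These floors cover counting error only, with each read taken as independent. Of the recovered counts above 0, 54.26% to 61.04% were even, and the source of this was not tested. If reads were not counted independently, the floors, the fold bounds and the tests on recovered reads understate the error. The DP values had no readable step, so their depth is unknown and no floor is given. Genes that every cell uses were also listed at 0 there: of 35 housekeeping genes, 7 and 7 in the uncultured, 12 and 9 in the co-cultured and 8 and 12 in the treated libraries. In the niche libraries 4 or 5 of the 35 were at 0 (4 and 4 in ZKS cells, 5 and 4 in pericytes, 5 and 4 in sinusoids). DP genes are therefore given as the value of each library, and a 0 means only that the gene is listed at 0.

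The groups, comparisons, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. The plan assumed read counts and named edgeR's quasi-likelihood test as the main test. Because the files held CPM, genes were instead tested with limma 3.58.1 in R 4.3.3 (trended empirical Bayes) on log2(CPM + 1) after TMM scaling with edgeR 4.0.16. A fold change on this scale understates the change of low genes. Genes needed at least 1 CPM in at least 2 libraries of a set, which left 15916 niche and 8795 DP genes. The 3 groups of a set shared 1 fit of 6 libraries with 3 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. SEs are the moderated errors of limma. The scaling moved the median log2 change of all genes by over 0.1 in 4 comparisons. With CPM as deposited in place of TMM, it went from -0.16 to 0.098 in ZKS cells against pericytes, from -0.087 to 0.033 in ZKS cells against sinusoids, from -0.011 to -0.12 in pericytes against sinusoids, and from -0.65 to -0.51 in treated against uncultured DP cells.

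Of the 32047 identifiers, 28978 had a symbol in the gene name table, in which many zebrafish genes carry the capital symbol of their orthologue. Copies that share a symbol are given with their identifier. Reads from near-identical copies could have been split by the authors' counting, so values of such copies are uncertain. No coordinates are given, because the annotation used here is of another build. The fixed lists covered niche factors, cell type markers, signalling targets, cell cycle, stress and metabolism, 30 for the niche and 28 for the DP set. Of 747 listed symbols, 531 matched as written, 163 after dropping the copy letter and 53 not at all. Lists with at least 5 tested members were tested against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. As an alternative, fry tested whether the genes of a list moved, on balance, one way; it compares them with no change and not with other genes, so its p does not answer the same question as camera's. With an estimated correlation per list, camera made 0 calls at an adjusted p under 0.05, against 77 with the preset value. The estimate came from 3 residual degrees of freedom. Lists with an estimate below the preset value lost their call as well. In ZKS cells against pericytes, cholesterol synthesis (estimate -0.0318) went from a camera adjusted p of 1.42e-10 to 0.123. For such lists the loss does not come from a larger correlation. Other lists had estimates far above the preset value. In the niche set these were 0.82 for G2/M, 0.58 for S phase, 0.786 for mitochondrially encoded and 0.732 for ribosomal protein genes. In the DP set they were 0.141, 0.225, 0.106 and 0.389 in the same order. If these estimates hold, camera's p at the preset value is too small for such lists. The adjusted p with an estimated correlation is given beside each list, as is the count of members adjusted over the list alone.

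The named genes of a comparison were the 6 with the largest change in each direction among those past the threshold, with a mean of at least 10 CPM in the higher group, no overlap between libraries and a gene symbol. Up to 4 members of each list with the smallest adjusted p past the threshold were added, with both directions where both occurred. A fixed set was always included: pdgfrb, stab2, cxcl12a, kitlga, thpo, csf3a, jag1a and jag1b in the niche, and gata2a, runx1, gata2b, myb, mpl, kitb, axin2, lef1, cish, mki67 and cdkn1a in the DP cells. Members of lists without a call in the DP set were chosen after their values were seen. A few genes that the rule names are not reported here.

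The alternative settings fixed in advance were median-of-ratios factors, no filter, a filter of 10 CPM, only the 4 libraries compared, all 12 libraries in one fit, a replicate block, a 2-fold minimum, leaving out mitochondrially encoded, haemoglobin and ribosomal protein genes, fry for lists, and leaving out each library in turn. DESeq2 1.42.0 was run on the reads recovered for the 3 niche comparisons. Pseudocounts of 0.1 and 5, CPM as deposited, and edgeR's quasi-likelihood test on the recovered reads of the same comparisons were chosen after seeing the data. The overlap of both co-culture comparisons, which share the uncultured libraries, was set beside 100 simulations of unchanged groups.

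The fit was tested on simulated data with 200 changed genes, 50 at each size, all drawn from genes above the median level of the set. Recovery of lower genes was not simulated. For pericytes against ZKS cells (15916 genes) it recovered 0%, 38%, 74% and 96% of genes changed by 1, 2, 3 and 5 log2 units, with 4 unchanged genes called. For co-cultured against uncultured DP cells (8795 genes) it recovered 0%, 0%, 0% and 4%, with 0 unchanged genes called.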

Results

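Messenger RNA was profiled in 12 libraries from the zebrafish kidney, the main adult blood-forming organ of fish. A niche set held ZKS cells, pericytes and sinusoids, and a second set held gata2a+ runx1+ double positive (DP) cells that were uncultured, co-cultured with ZKS cells, or co-cultured with ZKS cells plus IWR-1-endo and Thpo (n = 2 per group). ZKS is also the name of a cultured stromal line from zebrafish kidney; the labels call the profiled cells sorted and do not say whether they had been cultured. The 6 niche libraries held 6984492 to 16242092 reads, with 15545 to 20626 genes above 0. The depth of the DP libraries is unknown, and 7329 to 9712 genes were above 0 in them. Across genes, which are not independent replicates, log2 values of replicates correlated at 0.984 in ZKS cells, 0.9 in pericytes and 0.902 in sinusoids. In the DP groups the correlations were 0.579 in uncultured, 0.481 in co-cultured and 0.441 in treated cells, against 0.42 to 0.492 between DP groups.

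The genes behind each sort were read first. PDGFRB (ENSDARG00000100897), a receptor of mural and stromal cells, was at 125 ± 1.14 CPM (SD, n = 2) in pericytes, 31.3 ± 0.417 in ZKS cells and 2.17 ± 1.37 in sinusoids. The scavenger receptor gene stab2 (ENSDARG00000045748) was at 2918 ± 800 CPM in sinusoids, 11.02 ± 8.92 in pericytes and 1.43 ± 0.587 in ZKS cells, and its relative stab1 at 6214 ± 1100 CPM in sinusoids and 0.52 ± 0.127 in ZKS cells. In the uncultured DP libraries GATA2 (gata2a, ENSDARG00000059327) was at 45.3 and 177.5 CPM and RUNX1 (ENSDARG00000087646) at 6.3 and 6.1 CPM. In pericytes GATA2 was at 140.44 and 146.9 CPM and RUNX1 at 6.85 and 3.58 CPM. In sinusoids they were at 50.33 and 45.99 CPM and at 1.12 and 0.99 CPM, and in ZKS cells both were at 0. The levels of these genes therefore do not set the uncultured DP libraries apart from pericytes. Markers of blood cells differed between the niche groups. Haemoglobin genes summed to 0.11 and 0.3 CPM in the ZKS libraries, 699 and 1280.1 CPM in the pericyte libraries and 3923 and 1977 CPM in the sinusoid libraries. The macrophage and monocyte list summed to 4.33 and 5.75 CPM in ZKS cells, 4084 and 5489 CPM in pericytes and 1020 and 1311 CPM in sinusoids. Its gene cd74a alone was at 2432 and 3251 CPM in pericytes and 172 and 214 CPM in sinusoids. Of 16 tested members, 5 were above and 11 below the sinusoid level in pericytes. Among the latter, IRF8 was at 58.1 and 97.4 CPM in pericytes and 227 and 637 CPM in sinusoids. The sums therefore do not rank pericytes and sinusoids by macrophage content.

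**Figure D1:**
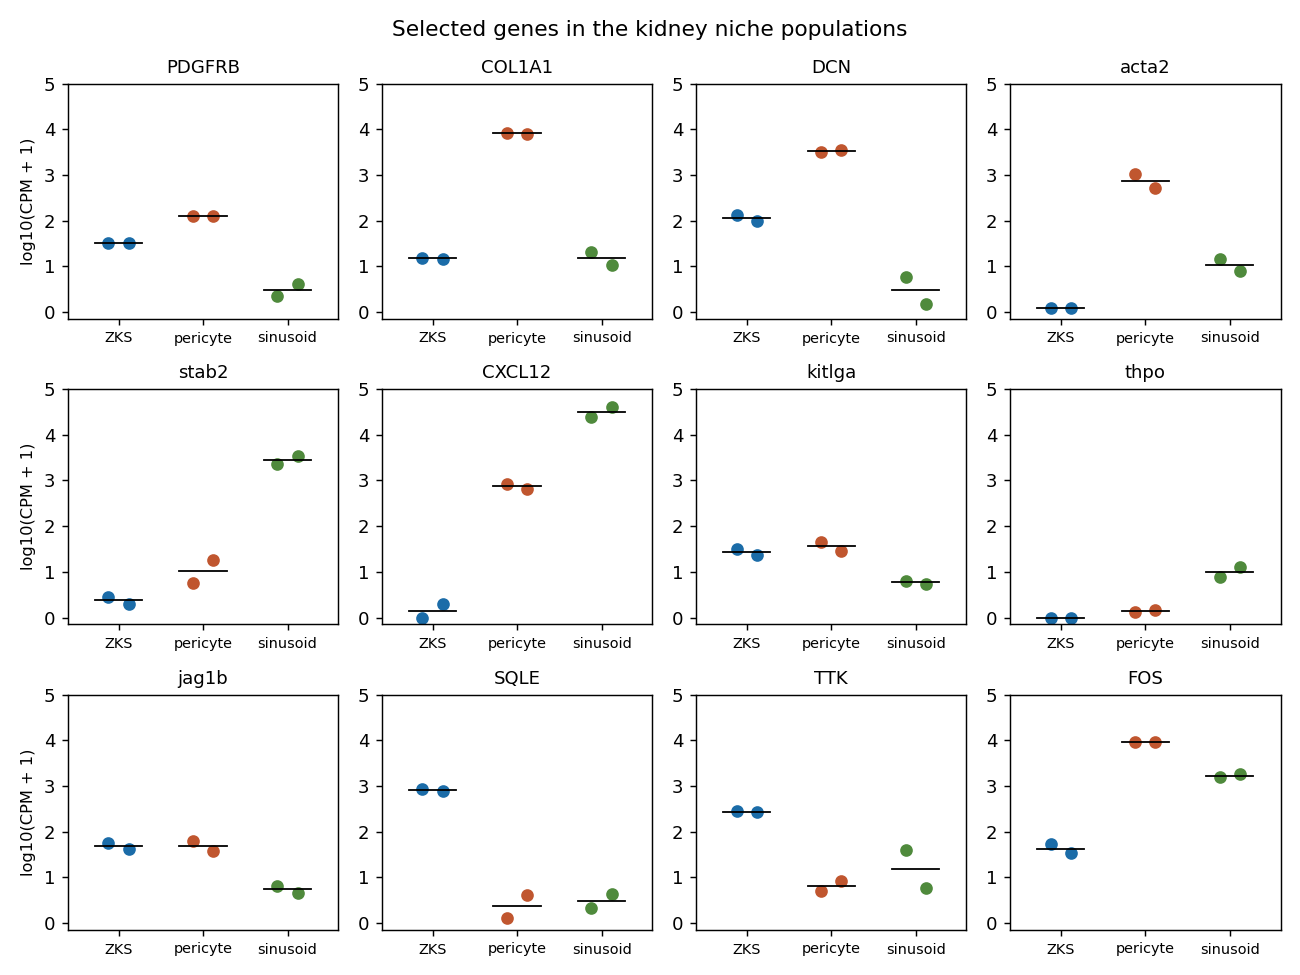
Expression of 12 genes in the 6 niche libraries, as log10(CPM + 1) on the vertical axis, with 1 point per library and a bar at the mean of both log values of each group. COL1A1 and DCN are highest in pericytes, stab2 and CXCL12 in sinusoids, and SQLE and TTK in ZKS cells.

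ZKS cells were compared with pericytes to ask how these stromal niche populations differ in expression. Genes of cholesterol synthesis and of the cell cycle were higher in ZKS cells, while stromal matrix, pericyte and mural, and immediate early and stress genes were lower. SQLE (ENSDARG00000079946), the squalene epoxidase of cholesterol synthesis, was at 822 ± 73.5 CPM (SD, n = 2) in ZKS cells and 1.72 ± 2.02 in pericytes, a log2 change of 8.18 ± 0.71 (SE, adjusted p = 0.000478). COL1A1 (ENSDARG00000035809), a chain of fibrillar collagen, was at 13.9 ± 0.269 CPM against 8132 ± 501 in pericytes (-9.46 ± 0.28, adjusted p = 2.53e-05). The chemokine gene CXCL12 (ENSDARG00000037116), which retains blood stem cells in the niche, was at 0.505 ± 0.714 CPM against 760.1 ± 135 (-9.27 ± 0.48, adjusted p = 9.87e-05).

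Of 23 tested genes of cholesterol synthesis, 19 rose in ZKS cells and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 1.42e-10; adjusted p = 0.123 with an estimated correlation). Besides SQLE they included FDPS, which makes farnesyl diphosphate, at 481 CPM against 20.8 (4.11 ± 0.28). Of 35 genes of the G2/M phases, 22 rose and 0 fell, or 27 and 0 adjusted over the list alone (camera adjusted p = 5.93e-09; adjusted p = 0.386 with an estimated correlation). The kinase genes TTK and CDK1 changed by 5.05 ± 0.73 and 4.84 ± 0.75. Of 33 S phase genes, 17 rose and 1 fell, or 20 and 1 adjusted over the list alone (camera adjusted p = 4.26e-07; adjusted p = 0.386 with an estimated correlation). The one that fell was DUT, which clears dUTP, at -2.65. With fry, the adjusted p of these cell cycle lists was 0.0632 for G2/M and 0.0719 for S phase. Of 26 glycolysis genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.000169; adjusted p = 0.187 with an estimated correlation), among them ENO1 (ENSDARG00000013750), at 6.10 ± 0.63, and GPI (ENSDARG00000012987), at 2.80 ± 0.33. Of 82 nuclear genes of oxidative phosphorylation 30 rose and 2 fell, or 31 and 2 adjusted over the list alone (camera adjusted p = 1.2e-08; adjusted p = 0.207 with an estimated correlation).

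Of 35 stromal matrix genes, 27 fell in ZKS cells and 2 rose, or 27 and 3 adjusted over the list alone (camera adjusted p = 3.86e-07; adjusted p = 0.123 with an estimated correlation). Of the fibronectin genes, the FN1 copy ENSDARG00000006526 was at 1.95 CPM in ZKS cells against 3348 in pericytes (-10.44 ± 0.29). The FN1 copy ENSDARG00000019815 stayed well expressed, at 290.25 and 308.18 CPM in the ZKS libraries against 1213.04 and 712.87 in the pericyte libraries. The stromal transcription factor gene PRRX1 (ENSDARG00000033971) rose, at 1010 against 83.2 CPM (3.23 ± 0.34). Of 22 pericyte and mural genes, 14 fell and 0 rose, or 15 and 0 adjusted over the list alone (camera adjusted p = 1.09e-05; adjusted p = 0.135 with an estimated correlation). The contractile genes acta2 and MYH11 (ENSDARG00000009782) changed by -9.47 ± 0.43 and -8.34 ± 0.61. PDGFRB itself changed by -2.33 ± 0.47 (adjusted p = 0.0097), and its adjusted p was 0.0738 without ZKS replicate 1, 0.0676 without ZKS replicate 2 and 0.0514 without pericyte replicate 2. Of 23 immediate early and stress genes, 18 fell and 0 rose, or 20 and 0 adjusted over the list alone (camera adjusted p = 2.69e-08; adjusted p = 0.187 with an estimated correlation). FOS was at 42.1 CPM in ZKS cells against 9334 in pericytes (-8.17 ± 0.36). SOCS3 (ENSDARG00000025428), a feedback inhibitor of cytokine signalling, was at 20.6 against 24160 CPM (-10.50 ± 0.41).

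Of 36 niche factors, 16 fell in ZKS cells and 1 rose, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.00148; adjusted p = 0.187 with an estimated correlation). The growth factor gene MDK (ENSDARG00000036036) was at 0 CPM in ZKS cells and 240.3 in pericytes, at least 742-fold lower, and the one that rose was BMP2 (ENSDARG00000041430), at 4.92 against 0 CPM. The stem cell factor gene kitlga (ENSDARG00000070917) was at 26.5 ± 5.64 CPM against 35.9 ± 11.8 (-0.77 ± 0.40, adjusted p = 0.173), and the Notch ligand gene jag1b (ENSDARG00000013168) at 47.8 ± 10.2 against 49.1 ± 16.6 (-0.38 ± 0.38, adjusted p = 0.458). Its relative jag1a (ENSDARG00000030289) was at 39.3 ± 2.48 against 13.2 ± 2.8 CPM (1.17 ± 0.50, adjusted p = 0.111), and passed the threshold with the 4 libraries alone (adjusted p = 0.0312), with CPM as deposited (adjusted p = 0.0421) and with DESeq2 (adjusted p = 0.0462). The gene thpo was at 0 CPM against 0.36, at or under the floor in both groups, and csf3a was too low to be tested. The gene stab2 changed by -2.37 ± 0.63 (adjusted p = 0.0257), with an adjusted p of 0.0785 without ZKS replicate 1, 0.124 without ZKS replicate 2 and 0.0992 without pericyte replicate 2, and of 0.0578 to 0.085 with no filter, a pseudocount of 5 or all 12 libraries in one fit. Of 16 macrophage genes 9 fell and 0 rose, or 9 and 0 adjusted over the list alone (camera adjusted p = 3.13e-05; adjusted p = 0.135 with an estimated correlation), among them cd74a at 0.31 CPM in ZKS cells against 2842 in pericytes. The alpha globin gene hbaa1 was at 0.055 against 193 CPM.

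Over all genes, limma called 5918 of 15916 between ZKS cells and pericytes, 2387 higher and 3531 lower in ZKS cells (40.3% higher). The largest increases included STC2 (ENSDARG00000056680), a secreted glycoprotein, at 11.04 ± 0.36, and EFEMP2 (ENSDARG00000094324), a matrix protein of elastic fibres, at 9.61 ± 0.49, and the largest decreases krt94 (ENSDARG00000044975), a keratin, at -12.73 ± 0.28, and cd34 (ENSDARG00000095268) at -10.54 ± 0.28. On the recovered reads of the 4 libraries compared, edgeR's quasi-likelihood test, chosen after seeing the data, called 5912 of 13712 genes. Of these 2260 were higher and 3652 lower, and 5261 were also called by limma in its fit of 6 libraries. On the same 4 libraries DESeq2 called 6736 and limma 6993. With CPM as deposited, 3168 of 6189 limma calls were higher (51.2%). The count was 1997 without ZKS replicate 1, 1861 without ZKS replicate 2, 3945 without pericyte replicate 1, 3742 without pericyte replicate 2 and 3536 with all 12 libraries in one fit.

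ZKS cells were next compared with sinusoids, vessel-lining cells titled by uptake of Ac-LDL. Endothelial, scavenger receptor and inflammatory genes were lower in ZKS cells, and cholesterol synthesis, cell cycle and bone and cartilage genes were higher. CXCL12 was at 32410 ± 10200 CPM (SD, n = 2) in sinusoids and 0.505 ± 0.714 in ZKS cells, a log2 change of -14.52 ± 0.48 (SE, adjusted p = 3.11e-05). The endothelial selectin gene sele (ENSDARG00000009123) was at 6289 ± 747 CPM in sinusoids and 0 in ZKS cells, at least 19400-fold lower. STC2 was at 3407 ± 74 CPM in ZKS cells and 0 in sinusoids, at least 15200-fold higher, and THBS4 (ENSDARG00000020072), a matrix glycoprotein of tendon and muscle, changed by 10.92 ± 0.32 (adjusted p = 2.52e-05).

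Of 23 pan-endothelial genes, 22 fell in ZKS cells and 0 rose, or 23 and 0 adjusted over the list alone (camera adjusted p = 5.08e-16; adjusted p = 0.174 with an estimated correlation). The junction genes cdh5 (740.1 CPM in sinusoids) and CLDN5 (ENSDARG00000014059; 759 CPM) were at 0 in ZKS cells, at least 2280-fold and 2340-fold lower. Of 21 sinusoidal scavenger genes 13 fell and 3 rose, or 14 and 4 adjusted over the list alone (camera adjusted p = 1.8e-05; adjusted p = 0.141 with an estimated correlation). The gene stab2 changed by -10.39 ± 0.63 (adjusted p = 0.000119) and the mannose receptor gene MRC1 by -12.09 ± 0.35, while LRP1 (ENSDARG00000097827), a receptor also used outside endothelium, was at 301 CPM in ZKS cells against 1.27 in sinusoids (adjusted p = 9.67e-05). Of 16 arterial genes 13 fell and 1 rose, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.141 with an estimated correlation). The Notch ligand gene dll4 was at 0.52 CPM in ZKS cells against 348 in sinusoids (-7.95 ± 0.38).

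Of 23 genes of cholesterol synthesis, 17 rose in ZKS cells and 1 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 3.47e-10; adjusted p = 0.141 with an estimated correlation). FDPS was at 481 CPM in ZKS cells against 28.0 in sinusoids (3.84 ± 0.28). Of 35 G2/M genes 14 rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 1.78e-06; adjusted p = 0.532 with an estimated correlation), with TTK at 3.95 ± 0.73. Of 33 S phase genes 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 4e-05; adjusted p = 0.532 with an estimated correlation). With fry the adjusted p was 0.134 for both cell cycle lists. The sinusoid libraries stood apart from each other here: the G2/M list summed to 2250 and 101.8 CPM in replicates 1 and 2 and the S phase list to 2653 and 788.8, with TTK at 39.3 and 4.74 CPM. In the ZKS libraries the sums were 4235 and 3930 CPM for G2/M and 5838 and 5915 CPM for S phase. Renal tubule genes, of another kidney cell type, summed to 2807 and 1127 CPM in the sinusoid libraries.

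Of 35 stromal matrix genes, 18 rose in ZKS cells and 8 fell, or 19 and 10 adjusted over the list alone (camera adjusted p = 0.00528; adjusted p = 0.174 with an estimated correlation). PRRX1 changed by 8.99 ± 0.34, PDGFRB by 3.16 ± 0.47 (adjusted p = 0.00324) and the collagen cross-linking enzyme LOX by 7.05 ± 0.30, whereas its relative LOXL1 was at 0.11 CPM in ZKS cells against 3261 in sinusoids (-11.58 ± 0.40). Among 36 niche factors 11 rose and 11 fell, or 11 and 12 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.842). The cytokine gene csf1b was at 0 CPM in ZKS cells and 649 in sinusoids, at least 2000-fold lower, and TGFB3 at 528 against 3.35 CPM (6.77 ± 0.50). The gene thpo (ENSDARG00000079158), which encodes thrombopoietin, was at 0 in ZKS cells and 9.32 ± 3.54 CPM in sinusoids, at least 28.8-fold lower (adjusted p = 0.00385). The Notch ligand genes jag1a and jag1b rose by 3.69 ± 0.50 (adjusted p = 0.00231) and 2.90 ± 0.38 (adjusted p = 0.00194). The gene kitlga was at 26.5 ± 5.64 CPM against 4.9 ± 0.58 (1.97 ± 0.40, adjusted p = 0.0107), with an adjusted p of 0.123 without ZKS replicate 1 and 0.0768 without ZKS replicate 2. Blood markers moved with these groups: of 15 erythroid genes 9 fell and 0 rose, or 10 and 0 adjusted over the list alone (camera adjusted p = 2.72e-05; adjusted p = 0.353 with an estimated correlation), with hbaa1 at 0.055 CPM in ZKS cells against 758 in sinusoids.

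Of 22 inflammatory genes, 17 fell in ZKS cells and 1 rose, or 19 and 1 adjusted over the list alone (camera adjusted p = 2.19e-08; adjusted p = 0.168 with an estimated correlation). The interleukin gene il1b was at 0 CPM in ZKS cells and 999 ± 197 in sinusoids, at least 3080-fold lower. The member that rose was MMP9, a matrix-cleaving enzyme that also stands in the neutrophil list, at 30070 CPM in ZKS cells against 379 (adjusted p = 0.00264, or 0.0765 with all 12 libraries in one fit). Leukocyte markers moved with the inflammatory genes. Of 16 macrophage genes 10 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 7.95e-07; adjusted p = 0.141 with an estimated correlation), with IRF8, a myeloid transcription factor gene, at 0.1 CPM in ZKS cells against 432 in sinusoids. Of 9 neutrophil genes 7 fell and 2 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.00528; adjusted p = 0.193 with an estimated correlation), with the oxidase subunit gene NCF1 at 0 against 769 CPM. Of 12 B cell genes 6 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00929; adjusted p = 0.187 with an estimated correlation), with the immunoglobulin gene ighm at 0 against 212 CPM. The B cell call ended without sinusoid replicate 1 (adjusted p = 0.219), without sinusoid replicate 2 (adjusted p = 0.0983) and with a filter of 10 CPM (adjusted p = 0.299). Of 15 genes of bone and cartilage, 8 rose in ZKS cells and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.000345; adjusted p = 0.193 with an estimated correlation). The homeobox gene DLX5, of bone-forming cells, was at 101 CPM in ZKS cells and 0 in sinusoids, at least 448-fold higher, and its relative DLX3 changed by 8.58.

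Of 20 Wnt targets, 7 rose in ZKS cells and 1 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0228, or 0.0769 without sinusoid replicate 2; adjusted p = 0.193 with an estimated correlation). Targets that rose included the deacylase gene notum1b, which removes a lipid from Wnt ligands (7.09 ± 0.41), and CCND1, a cyclin (3.56), while MYC (ENSDARG00000007241) fell, at -2.58. Of 20 Wnt ligands and modulators, 4 rose and 0 fell, or 4 and 0 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.487). The median of that list was -0.19 and its mean 0.71. The 4 included secreted inhibitors of Wnt signalling, WIF1 at 217 CPM against 0.125 (7.37 ± 0.70) and dkk1a at 44.6 against 0.

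Over all genes, limma called 5025 of 15916 between ZKS cells and sinusoids, 2259 higher and 2766 lower in ZKS cells (45.0% higher). With CPM as deposited, 2633 of 5161 calls were higher (51.0%). On the recovered reads of the 4 libraries compared, edgeR, chosen after seeing the data, called 4951 of 14032 genes. Of these 1977 were higher and 2974 lower, and 4381 were also called by limma in its fit of 6 libraries. On the same 4 libraries DESeq2 called 5997 and limma 6069. The limma count was 1852 without ZKS replicate 1, 1763 without ZKS replicate 2 and 2665 with all 12 libraries in one fit. That fit ended the calls of jag1b (adjusted p = 0.0712), MYC (adjusted p = 0.448) and FDPS (adjusted p = 0.0516).

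Pericytes were then compared with sinusoids, the cell pair that forms the wall of small vessels. Genes of the stromal matrix, Wnt ligands and modulators, and immediate early and stress genes were higher in pericytes, and endothelial and scavenger receptor genes were higher in sinusoids. COL1A1 was at 8132 ± 501 CPM (SD, n = 2) in pericytes and 14.9 ± 7.24 in sinusoids, a log2 change of 9.22 ± 0.28 (SE, adjusted p = 7.85e-05). Decorin, DCN (ENSDARG00000012066), a collagen-binding proteoglycan, was at 3353 ± 185 against 2.72 ± 3.15 CPM (10.35 ± 0.53, adjusted p = 0.000136). PDGFRB changed by 5.49 ± 0.47 (adjusted p = 0.000651) and stab2 by -8.02 ± 0.63 (adjusted p = 0.00046), each in the direction of its sort.

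Of 35 stromal matrix genes, 27 rose in pericytes and 4 fell, or 27 and 4 adjusted over the list alone (camera adjusted p = 5.65e-12; adjusted p = 0.106 with an estimated correlation). COL1A2 changed by 8.76 ± 0.35, and LOXL1, at 131 CPM in pericytes against 3261 in sinusoids, by -4.53 ± 0.40. Of 22 pericyte and mural genes 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.63e-06; adjusted p = 0.158 with an estimated correlation). NOTCH3, a receptor of mural cells, changed by 6.07 and TAGLN (ENSDARG00000045408), an actin-binding protein, by 6.78, while the adhesion molecule gene MCAM, known also from endothelium, was at 3.57 CPM in pericytes against 216 in sinusoids (-5.63). Of 23 pan-endothelial genes 19 fell and 0 rose, or 21 and 0 adjusted over the list alone (camera adjusted p = 1.25e-13; adjusted p = 0.248 with an estimated correlation), with cdh5 at -7.36 and CLDN5 at -7.84. Of 21 scavenger genes 13 fell and 3 rose, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.000473; adjusted p = 0.158 with an estimated correlation). The gene stab1 changed by -9.29 ± 0.43 and MRC1 (ENSDARG00000102100) by -9.60 ± 0.35, while LRP1 rose, at 9.33.

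Of 20 Wnt ligands and modulators, 15 rose in pericytes and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.03e-07; adjusted p = 0.158 with an estimated correlation). RSPO3, which strengthens Wnt signals, was at 65.7 ± 25.1 CPM against 0.945 (5.19 ± 0.53), and the Wnt-binding inhibitors SFRP1 (ENSDARG00000035521) and frzb at 57.6 against 1.38 CPM (4.76) and 54.9 against 0.41 CPM (5.46). Of 20 Wnt targets 9 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.000207; adjusted p = 0.158 with an estimated correlation), with notum1b at 5.11 ± 0.41 and MYC at 3.10 ± 0.40. Of 23 immediate early and stress genes 18 rose and 1 fell, or 19 and 3 adjusted over the list alone (camera adjusted p = 2.63e-06; adjusted p = 0.254 with an estimated correlation). The transcription factor gene egr1 was at 2503 against 175 CPM (3.95 ± 0.30), and the one that fell was the chaperone gene HSPA8 (ENSDARG00000068992), at -2.43, with an adjusted p of 0.0947 without pericyte replicate 1 and 0.137 without sinusoid replicate 2, and of 0.0591 to 0.124 with no filter, all 12 libraries in one fit or edgeR.

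Of 36 niche factors, 20 rose in pericytes and 7 fell, or 20 and 8 adjusted over the list alone (camera adjusted p = 0.00841, or 0.0726 without pericyte replicate 2; adjusted p = 0.254 with an estimated correlation). Among those higher in pericytes, ANGPTL1, an angiopoietin-like secreted protein, was at 264 ± 47.5 CPM against 0.15 (8.04 ± 0.38) and BMP4 at 114 ± 5.01 against 0.505 (6.40). The gene kitlga was at 35.9 ± 11.8 CPM against 4.9 ± 0.58 (2.74 ± 0.40, adjusted p = 0.00434) and jag1b at 49.1 ± 16.6 against 4.59 ± 1.44 (3.29 ± 0.38, adjusted p = 0.00186). For jag1a the change was 2.52 ± 0.50 (adjusted p = 0.0131), with an adjusted p of 0.0577 without pericyte replicate 1, 0.0555 with the 4 libraries alone and 0.112 with edgeR. Higher in sinusoids were CXCL12, at 32410 ± 10200 CPM against 760.1 ± 135 in pericytes (-5.26 ± 0.48, adjusted p = 0.000853), and csf1b (-8.58 ± 0.66). The gene thpo was at 0.36 ± 0.099 CPM in pericytes against 9.32 ± 3.54 in sinusoids (-2.88 ± 0.52, adjusted p = 0.00951, or 0.0682 with edgeR). Of 15 erythroid genes 5 fell and 0 rose, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0031, or 0.108 with fry; adjusted p = 0.546 with an estimated correlation). The macrophage list did not pass (camera adjusted p = 0.612), with 4 members higher and 3 lower in pericytes.

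Over all genes, limma called 4009 of 15916 between pericytes and sinusoids, 2389 higher and 1620 lower in pericytes. On the recovered reads of the 4 libraries compared, edgeR's quasi-likelihood test, chosen after seeing the data, called 1226 of 14888 genes. Of these 819 were higher and 407 lower in pericytes, and all 1226 were also called by limma in its fit of 6 libraries. On the same 4 libraries DESeq2 called 3057 and limma 2378. The limma count was 2454 without pericyte replicate 1, 1885 without pericyte replicate 2, 2512 without sinusoid replicate 2 and 2378 with the 4 libraries alone. All 12 libraries in one fit ended the calls of MYC (adjusted p = 0.354) and egr1 (adjusted p = 0.0609).

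Co-cultured DP cells were compared with uncultured ones to see how expression differed after culture on ZKS cells. Genes of the G2/M and S phases and immediate early genes were lower in the co-cultured libraries, and the list of blood stem and progenitor cell regulators did not pass the test. Genes of the G2/M phases summed to 1384 and 2084 CPM in the uncultured libraries and to 96.6 and 0.8 CPM in the co-cultured ones (n = 2 per group). In co-cultured replicate 1 the members CDC20 and AURKB were at 64.5 and 27.9 CPM, and in replicate 2 at 0.1 and 0. The proliferation marker gene mki67 (ENSDARG00000091150) was at 163.8 and 138.1 CPM uncultured and 0.1 and 0 co-cultured. The cell cycle inhibitor gene cdkn1a (ENSDARG00000076554) was also listed at 0 in both co-cultured libraries, against 51.2 and 52.8 CPM uncultured. Immediate early and stress genes summed to 13800 and 13390 CPM uncultured against 485.9 and 627.8 CPM co-cultured.

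No single gene passed the test between co-cultured and uncultured cells. Of 8795 genes limma called 0, with 995 at an unadjusted p under 0.05 where chance gives 440, and a smallest adjusted p of 0.168. With all 12 libraries in one fit the count was 635, of which 100 were higher. That fit mixes the spread of the DP libraries with that of the more alike niche replicates, so these are not taken as changed genes. As a group, the 20 tested G2/M genes fell (camera adjusted p = 3.93e-16; adjusted p = 0.2 with an estimated correlation). Adjusted over the list alone 18 of them fell, against 0 over all genes. Examples, chosen after their values were seen, were CCNB1, a mitotic cyclin, at 85.9 and 116.6 CPM uncultured against 0.1 and 0, and TOP2A at 197.5 and 430 against 0.1 and 0.1. The filter left 20 of the 37 listed G2/M genes. Some of these, such as CDK1 and ASPM, were listed at 0 in all co-cultured and treated libraries. They passed the filter through the uncultured libraries alone and could only fall. Counts and tests of this and the other DP lists therefore lean toward a fall. The G2/M sums cover all 37 genes and do not depend on the filter. The 30 tested S phase genes fell as a group, 11 of them adjusted over the list alone against 0 over all genes (camera adjusted p = 2.08e-09; adjusted p = 0.602 with an estimated correlation). TYMS, which makes thymidylate, was at 307.9 and 362.1 CPM uncultured against 0 and 0.4, whereas MCM5, a subunit of the replicative helicase, was at 985.5 and 246.3 against 211.4 and 575.4. Of 19 immediate early and stress genes 11 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 5.7e-11; adjusted p = 0.117 with an estimated correlation). FOS was at 2134.9 and 1706.2 CPM uncultured against 0.9 and 0.3, and DUSP1, a phosphatase of MAP kinases, at 3555.8 and 3318.4 against 9.4 and 77.5.

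Targets of JAK-STAT signalling, which share both JUNB copies with the immediate early and stress genes, were also lower after co-culture. The JAK-STAT list summed to 10820 and 11050 CPM uncultured and 1731 and 1583 CPM co-cultured, and 5 of 19 tested members fell adjusted over the list alone, 0 over all genes (camera adjusted p = 0.0306; adjusted p = 0.637 with an estimated correlation). Its adjusted p was 0.139 without uncultured replicate 1, 0.103 without co-cultured replicate 2 and 0.142 with fry. SOCS3 (ENSDARG00000025428) was at 3634.8 and 4597.2 CPM against 10.1 and 209.2, and CISH (ENSDARG00000060316), another cytokine-induced inhibitor, at 35.4 and 107 against 0 and 0. Regulators of stem and progenitor cells summed to 7357 and 6385 CPM uncultured and 7591 and 7832 CPM co-cultured, and the list did not pass (camera adjusted p = 0.554; adjusted p = 0.743 with an estimated correlation). Its members went both ways, 12 above and 13 below the uncultured level, and 0 of 25 were called over all genes or adjusted over the list alone. The median was -0.09 and the mean -0.38, while camera's direction was up. The 6 with the smallest p were RUNX1, at 6.3 and 6.1 CPM uncultured against 0.1 and 0 (adjusted p = 0.168), egr1, also an immediate early gene, at 589.1 and 508.8 against 22 and 0 (adjusted p = 0.18), and 4 more. CEBPA was at 277.8 and 508.1 CPM uncultured against 1409.9 and 1266.7 (adjusted p = 0.192), LMO2 at 133 and 117.1 against 497.2 and 456.6 (adjusted p = 0.233), and gfi1aa at 0.1 and 1 against 516 and 358.5 (adjusted p = 0.276). The chemokine receptor gene CXCR4 was at 2153.5 and 1463.5 CPM uncultured against 286.3 and 684.1 (adjusted p = 0.216). GATA2 was at 45.3 and 177.5 CPM against 33.1 and 127.9, gata2b at 325.2 and 85.5 against 66 and 20.7, and MYB at 146.1 and 176.3 against 184.1 and 137.3. The thrombopoietin receptor gene mpl was at 79.3 and 53.1 CPM against 65.7 and 77.1. Among other cell types, macrophage genes summed to 4179 and 5340 CPM uncultured and 4468 and 6434 CPM co-cultured. Of these sums cd74a alone made up 2883.9 and 3262.1 CPM uncultured and 2942.1 and 4986.5 CPM co-cultured. Erythroid genes summed to 65.4 and 13.6 CPM against 3.3 and 250.2. Stromal matrix genes, which the feeder cells also express, summed to 160.1 and 134.1 CPM against 168.3 and 229. Thrombocyte genes summed to 594.4 and 469.4 CPM uncultured and 285.7 and 415.7 CPM co-cultured, with itga2b, an integrin gene of thrombocytes, at 36.9 and 63.5 against 0 and 0 CPM, and 1 of 9 members fell adjusted over the list alone, 0 over all genes. Neutrophil genes summed to 261.1 and 440.1 CPM against 83.8 and 412.4, and of 6 members 1 rose and 1 fell adjusted over the list alone, 0 over all genes. Neither list passed (camera adjusted p = 0.477 for thrombocyte and 0.774 for neutrophil genes; adjusted p = 0.739 and 0.851 with an estimated correlation). The uncultured libraries listed 9712 and 9541 genes above 0 and the co-cultured ones 7553 and 7676.

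**Figure D2:**
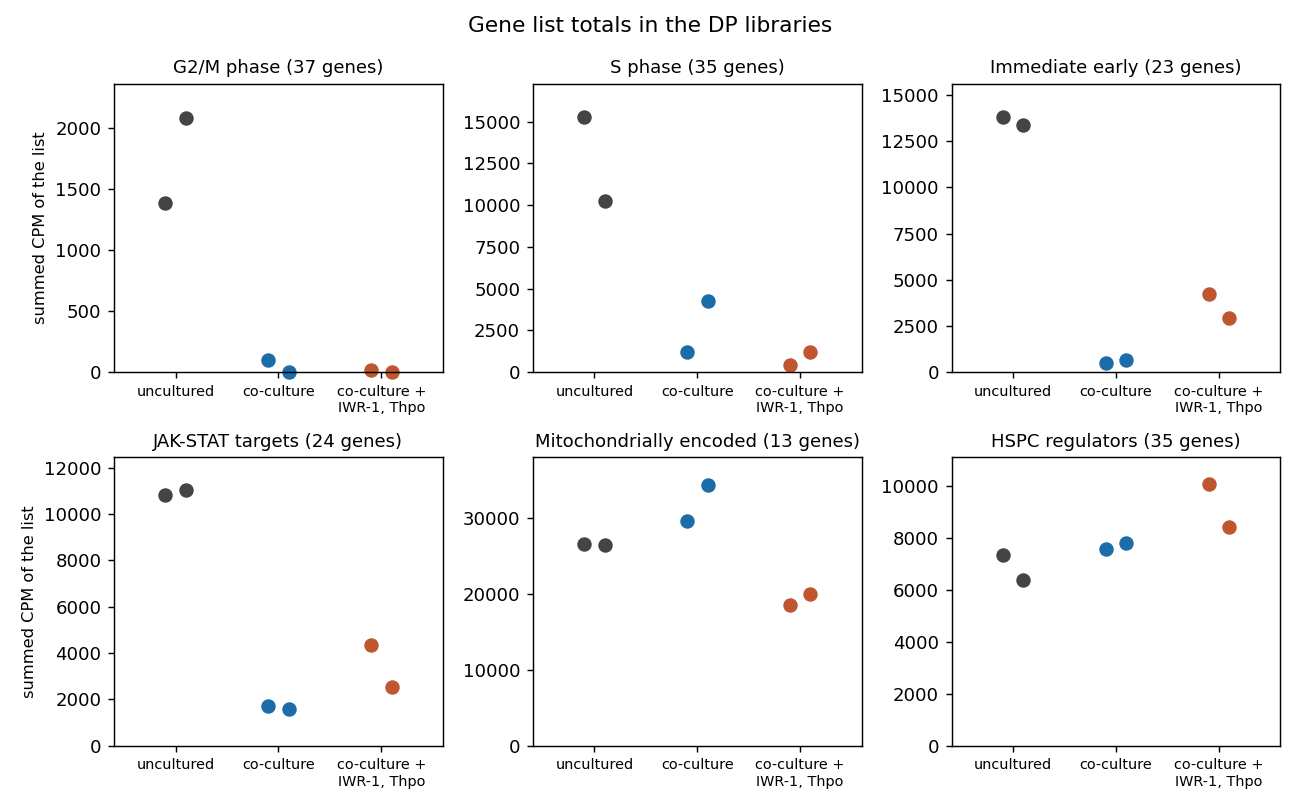
Summed CPM of 6 gene lists (vertical axes, linear, from 0) in the 6 DP libraries, with 1 point per library in each of 3 groups. The G2/M list is at 1384 and 2084 CPM in uncultured cells and at or under 96.6 CPM in the other 4 libraries, and the mitochondrially encoded list is lowest in the treated group.

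Co-cultures with IWR-1-endo, a tankyrase inhibitor that dampens Wnt signalling, and Thpo, the ligand of mpl, were compared with co-cultures without them. Mitochondrially encoded genes were lower in the treated cells, and some of the immediate early genes were higher. The 13 mitochondrially encoded genes summed to 29550 and 34390 CPM in co-cultured and 18610 and 20020 CPM in treated libraries (n = 2 per group). Immediate early and stress genes summed to 485.9 and 627.8 CPM in co-cultured and 4240 and 2923 CPM in treated libraries. The Wnt target gene AXIN2 was listed at 0 in all of these libraries, and LEF1, a Wnt transcription factor, at 4.6 CPM in treated replicate 2 and 0 in the others. The stem cell factor receptor gene kitb was listed at 0 as well.

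Of 8795 genes limma called 0 between treated and untreated co-cultures, with 842 at an unadjusted p under 0.05 where chance gives 440, and a smallest adjusted p of 0.291. With all 12 libraries in one fit, which mixes in the spread of the niche libraries, the count was 486, of which 195 were higher. Mitochondrially encoded genes fell as a group, 8 of 13 adjusted over the list alone and 0 over all genes (camera adjusted p = 3.95e-09, or 0.0693 with fry; adjusted p = 0.437 with an estimated correlation). MT-ND4 was at 2516.3 and 2571.6 CPM in co-cultured against 910 and 1184.4 in treated cells, and MT-ATP6 at 1291.3 and 1630.8 against 449.8 and 222.6. The 19 immediate early genes rose as a group, 3 of them adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00526, or 0.437 with an estimated correlation). The members were mixed, with 12 above and 5 below the co-cultured level, a median of 0.257 and a mean of 1.76. That list's adjusted p was 0.0878 without treated replicate 1 and 0.0693 with fry. FOS was at 0.9 and 0.3 CPM in co-cultured against 452.2 and 150.7 in treated cells, and DUSP1 at 9.4 and 77.5 against 1507.1 and 1900.2. The list of 7 tested Wnt targets did not pass (camera adjusted p = 0.965), nor did JAK-STAT targets (camera adjusted p = 0.189), which summed to 1731 and 1583 CPM in co-cultured against 4344 and 2543 in treated cells. CISH was at 0 and 0 against 133.4 and 0 CPM, and mpl at 65.7 and 77.1 against 99.6 and 30.9. The share of ribosomal protein genes was 12.5% and 16.4% in co-cultured and 10.4% and 11.7% in treated libraries.

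Ribosomal protein, oxidative phosphorylation and S phase genes were also lower as groups in treated than in co-cultured cells. Of 72 ribosomal protein genes 0 were called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000127; adjusted p = 0.874 with an estimated correlation). Its adjusted p was 0.223 without co-cultured replicate 2, 0.18 without treated replicate 1 and 0.5 with fry. Of 65 nuclear genes of oxidative phosphorylation, which summed to 8890 and 9705 CPM in co-cultured and 5601 and 6208 CPM in treated libraries, 0 were called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00237; adjusted p = 0.691 with an estimated correlation). That list had an adjusted p of 0.223 without co-cultured replicate 2, 0.0878 without treated replicate 1 and 0.225 with fry. Of 30 S phase genes 2 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0294; adjusted p = 0.874 with an estimated correlation), with sums of 1227 and 4267 CPM in co-cultured and 444.7 and 1198 CPM in treated libraries. Without co-cultured replicate 2 the S phase list was at an adjusted p of 0.621, without treated replicate 1 at 0.233 and with fry at 0.305. MCM5 was at 211.4 and 575.4 CPM in co-cultured and 0 and 0 in treated libraries.

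Treated co-cultures were also compared with uncultured cells. Genes of the G2/M phases were lower in the treated cells too, with the list at 17.3 and 0.9 CPM against 1384 and 2084 uncultured. The S phase list summed to 444.7 and 1198 CPM in treated and 15250 and 10230 CPM in uncultured libraries. Both mki67 and cdkn1a were listed at 0 in the treated libraries, and RUNX1 was as well. GATA2 was at 319.8 and 9.1 CPM in treated cells, gata2b at 431.9 and 134.4, and MYB at 226.8 and 315.4. All 20 tested G2/M genes fell adjusted over the list alone and 0 over all genes (camera adjusted p = 2.79e-14; adjusted p = 0.23 with an estimated correlation), as did 20 of 30 S phase genes adjusted over the list alone and 0 over all genes (camera adjusted p = 1.63e-14; adjusted p = 0.23 with an estimated correlation). Here too, members that passed the filter through the uncultured libraries alone could only fall, so these counts lean toward a fall. PCNA, the sliding clamp of DNA replication, was at 3249.9 and 1260.2 CPM uncultured against 0.5 and 0.3. Immediate early genes were below the uncultured level, with 4 of 19 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 2.28e-05; adjusted p = 0.23 with an estimated correlation). Mitochondrially encoded genes fell, 7 of 13 adjusted over the list alone and 0 over all genes (camera adjusted p = 4.08e-06; adjusted p = 0.23 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell as a group, 1 of 65 adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00283, or 0.0601 with fry; adjusted p = 0.518 with an estimated correlation). Genes of the unfolded protein and integrated stress responses fell too, 1 of 19 adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0116, or 0.0822 without treated replicate 1; adjusted p = 0.23 with an estimated correlation). The ribosomal protein list was lower, with 0 of 72 members called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.798 with an estimated correlation). That call ended with CPM as deposited (adjusted p = 0.565), median-of-ratios factors (0.502), a filter of 10 CPM (0.104), all 12 libraries in one fit (0.119), and without uncultured replicate 2 (0.126) or treated replicate 1 (0.688). With fry, a test against no change, the adjusted p was 0.271. Regulators of stem and progenitor cells summed to 10110 and 8439 CPM in treated against 7357 and 6385 CPM in uncultured libraries and did not pass (camera adjusted p = 0.399), with 12 members above and 13 below the uncultured level, a median of -0.43, a mean of -0.62 and camera's direction up. Of 8795 genes limma called 0, with 1183 at an unadjusted p under 0.05 where chance gives 440, and a smallest adjusted p of 0.144. With all 12 libraries in one fit, which mixes in the spread of the niche libraries, the count was 814, of which 127 were higher. The treated libraries listed 7834 and 7329 genes above 0.

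Both co-culture groups were set against the same uncultured libraries, so their changes share chance values. Of the genes called by limma, 0 were shared, with 0 in the simulations and 0 for independent lists. At an unadjusted p under 0.05, 586 of 8795 genes changed the same way in both, against a median of 160 (range 125 to 192) in simulations of unchanged groups and 93.4 for independent lists. Of these, 547 were lower in both (78 simulated, 88.9 independent). The log2 changes correlated across genes at 0.479, against 0.499 in the simulations, and their covariance was 2.68 against 2.35 (range 2.13 to 2.55). The uncultured group had only 2 libraries and could not be split. The simulations held the same sharing of controls, but with normal noise. They left out the lower number of genes above 0 in the co-culture libraries (7329 to 7834, against 9712 and 9541 uncultured). Whether the excess comes from such differences was not tested, so it is not read as a shared response.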

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

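CPM as deposited, the pseudocounts of 0.1 and 5 and edgeR's test on recovered reads were chosen only after the results were seen; the other settings were fixed before. Leaving out 1 library leaves its group a lone sample, which is assumed to vary like the other groups. Over all settings, 104 counts of genes or lists stayed within 1.5 times the reported value and 17 did not; 1062 list results stayed on their side of the threshold, 163 lost their call and 1 turned direction; 5264 results for named genes stayed on their side, 469 lost their call and 3 gained one. The 104 include the DP counts and the DP overlap, which stayed at 0 in all settings but the fit of all 12 libraries. These could hardly move, since at most 4% of simulated DP changes were recovered. They also include totals of list calls that were partly carried over from the reported fit. The results for named genes cover the niche comparisons only. The cause of a move was not tested unless stated. Leaving out each library in turn gave 1861 to 3945 genes for ZKS cells against pericytes (5918 with all), 1763 to 4632 for ZKS cells against sinusoids (5025) and 1885 to 3895 for pericytes against sinusoids (4009), with fewer samples in each fit. The lowest count of each came without ZKS replicate 2, ZKS replicate 2 and pericyte replicate 2, and the DP counts were 0 each time. With all 12 libraries in one fit the niche counts were 3536, 2665 and 2742, and the DP counts, reported as 0, were 635, 486 and 814. That fit uses 1 spread for both sets. Replicates correlated at 0.9 to 0.984 in the niche groups and at 0.441 to 0.579 in the DP groups. The DP counts from that fit are therefore not taken as changed genes. Pericytes against sinusoids gave 2378 genes with limma on only the 4 libraries. On the same 4 libraries edgeR gave 1226 and DESeq2 3057. An estimated correlation left 0 of 77 list calls, where the estimate itself rests on few degrees of freedom; fry, which tests another null, kept 58 of the 77, lost 19 and made 72 calls in all. With a library left out, only the comparisons of its group were run again, and the list calls of the others were carried over. The total of list calls is therefore no measure of those settings.

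The G2/M list was lower in pericytes than in sinusoids (camera adjusted p = 0.0496) and turned direction without sinusoid replicate 1 (adjusted p = 0.0972). Leaving out each library gave 1.43e-11 to 0.229, and the adjusted p over all settings reached 0.828 with an estimated correlation. Deviations of samples with the same replicate number correlated at -0.013 to 0.0638 across genes. These values show no broad shift shared by replicate number, but they cannot exclude a shared animal or day. With the replicate number as a replicate block, 5768, 4852 and 3765 genes were called in the niche comparisons and 0 in each DP comparison, with 79 list calls. DESeq2 was not run for the DP comparisons or their overlap, since it needs reads that were not recovered there. In the DP libraries the unknown depth keeps a value of 0 from being read as absence.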

Other observations

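The tests of explanations weighed here were all chosen only after the results were seen; the list tests of the first paragraph were fixed before.

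Further lists separated pericytes from sinusoids. Of 9 podocyte genes, known from the kidney filter, 7 rose in pericytes and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 2.96e-05; adjusted p = 0.254 with an estimated correlation). The transcription factor gene wt1b was at 72.3 ± 13.9 CPM (SD, n = 2) against 0.16 in sinusoids, a log2 change of 6.11 ± 0.51 (SE), and the junction gene KIRREL1 at 74.7 ± 6.13 against 1.05 (5.34 ± 0.43). Of 22 inflammatory genes, 10 fell in pericytes and 3 rose, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.0031, or 0.05 without sinusoid replicate 2; adjusted p = 0.277 with an estimated correlation). The interleukin gene il1b was at 18.1 ± 10.9 CPM in pericytes against 999 ± 197 in sinusoids (-5.70 ± 0.51), while the prostaglandin synthase gene PTGS2 was at 294 ± 130 against 18.2 ± 10.3 (adjusted p = 0.00492). Of 23 interferon response genes 8 fell and 0 rose, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.00247; adjusted p = 0.254 with an estimated correlation). The antiviral gene mxc was at 0.285 CPM in pericytes against 25.4 ± 10.9 in sinusoids (-4.34 ± 0.53). Among leukocyte markers, of 9 neutrophil genes 4 fell in pericytes and 0 rose, or 4 and 0 adjusted over the list alone, and that list did not pass (camera adjusted p = 0.0624; adjusted p = 0.366 with an estimated correlation). Of 12 B cell genes 5 fell and 2 rose, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.254 with an estimated correlation). The B cell list had an adjusted p of 0.0837 without pericyte replicate 1, 0.0915 without pericyte replicate 2, 0.502 without sinusoid replicate 1, 0.347 without sinusoid replicate 2 and 0.96 with a filter of 10 CPM.

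Genes of the G2/M and S phases were lower in both co-cultured DP groups than in uncultured cells. A general loss of detected genes in the co-culture libraries, falling alike on genes of the same uncultured level, was argued against. The highest percentile of either list, in either comparison, among 10000 random lists matched on uncultured level was 0. Those lists held genes drawn independently, so they could not test a joint loss of co-expressed genes, which stays open. Cycling blood cells of another lineage in the uncultured sort could also give the pattern, although the gata2a+ runx1+ gate should remove them; the lowest percentile of a lineage list was 16.9, for 9 thrombocyte genes, with 25.8 for 5 erythroid, 18.9 for 6 neutrophil and 66.3 for 6 macrophage genes. The few members leave that explanation open, and the B and T cell lists had too few to be tested. A slower cell cycle after co-culture, the difference the design names, also stays open and was not tested.

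Cell cycle genes stood higher in sinusoid replicate 1 than in replicate 2, with G2/M genes at 2250 and 101.8 CPM in sum and S phase genes at 2653 and 788.8 CPM. Fewer reads in replicate 2 were argued against, since its recovered depth was 16.2, against 13.4 in replicate 1, in units of 1e+06 reads. Replicate 2 still listed fewer genes above 0, at 16474 against 20626 in replicate 1. Reads copied by PCR are not independent molecules, so fewer molecules in replicate 2 are not excluded by its depth. Red blood cell precursors in replicate 1 may have added to the cell cycle signal. The erythroid list, of 16 genes with 0 in another list, lay at percentile 100 of matched random lists. Among its members hbaa1 was at 1032 against 483 CPM and SLC4A1 at 846 against 188 CPM. Kidney tubule cells in replicate 1 may have added to that signal as well. The renal tubule list, of 24 genes with 0 in another list, also lay at percentile 100. Among its members atp1a1a.4 was at 573 against 0.86 CPM and CDH17 at 366 against 0.12 CPM. The neutrophil list lay at percentile 100 too. In both pericyte libraries, 13 of the erythroid and 12 of the tubule genes were at 1 CPM or more. The Ac-LDL gate should leave all these cell types out. The source of the cycling signal is therefore not settled, and a difference in the sinusoid cells themselves was not tested.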
